A study of Homo sapiens with 32 samples.

How the data were processed

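RNA sequencing of 32 libraries from the human lymphoma lines TMD8 and DOHH2 was analysed, 16 libraries per line. Per the labels, cells engineered with Cas9 were grown in advanced RPMI with 5% FBS and treated with 500 nM CSKi or DMSO for 1, 3, 6 or 24 h, RNA was extracted with RNeasy, and TruSeq stranded mRNA libraries were sequenced as paired 75 base reads. Groups were line, treatment and time, with 2 libraries in each of 16 groups. The sample titles call the duplicates bio replicates 1 and 2, and do not say further whether they are separate cultures.

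Per the submitters' processing notes, reads were assigned to hg19 and counted with HTSeq. The version of HTSeq, its strand setting and the aligner are not given in the sources used here. The deposited values are log2 of counts multiplied by a factor for each library, with 0 for no reads, in a table of 25066 features, as the values themselves show. Dividing each library by the value of 1 read gave whole numbers within 0.1 reads for 98.2 to 100% of values up to 300 reads, and these recovered reads summed to 0.9998 to 1.0001 of the total mapped reads in the table. How the authors derived the factor is not given in the sources used here. It tracked median of ratios, upper quartile and total mapped scaling with coefficients of variation of 1.42, 1.11 and 1.66%, and matched none of them exactly. The row of total mapped reads was left out of all tests. Libraries held 12273442 to 24907030 mapped reads, with 16973020 and 17420599 as the middle values. At the lowest mean tested, 20.6 reads per library in TMD8 and 14.5 in DOHH2, sampling alone gives a coefficient of variation over 20%. Gene IDs of 21304 features matched a current symbol, and 3918 of these have been renamed since. The GRCh38 annotation was used only for names and for transcript GC content and length (GENCODE v29), and no coordinate was used.

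The deposited log2 values were fitted by limma 3.58.1 in R 4.3.3 (with jsonlite 2.0.0) as a model of group means, with eBayes(trend=TRUE), two-sided tests and Benjamini-Hochberg adjustment over the 12000 features with the highest mean, and a gene was called at adjusted p under 0.05. Treatment contrasts came from a fit of the 16 libraries of a line (8 residual degrees of freedom), and line differences and the vehicle difference of the lines from a fit of all 32 (16 degrees of freedom, lowest mean 15.3 reads). Changes of the response and of vehicle over time were tested by F tests of 3 contrasts against 1 h. No vehicle library is shared between times. Gene lists were tested by camera with the preset correlation of 0.01, adjusted over 216 tests of lists with at least 5 members tested. The 32 lists were immediate early, ERK feedback, NF-kB target, cytokine and chemokine, B cell activation, B cell receptor pathway, Src family kinase and regulator, FOXO target, MYC and ribosome biogenesis, cholesterol and fatty acid synthesis, ATF4 and amino acid response, unfolded protein response, heat shock, p53 target, G2/M, G1/S, BCL2 family, plasma cell differentiation, germinal centre, activated B cell type, interferon response, STAT3 and SOCS, glycolysis and hypoxia, MHC class II, actin and adhesion, B cell migration, ribosomal protein, mitochondrially encoded and histone genes, and markers of T and NK cells, myeloid cells, and fibroblasts and epithelium. "Adjusted over the list alone" is Benjamini-Hochberg adjustment of the unadjusted limma p within 1 list. Overlaps of calls were set against independent lists and tested by Fisher's exact test. Figures were drawn with matplotlib 3.10.9, and pandas 2.3.3 in Python 3.11.15 made tables.

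The contrasts, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names up to 5 genes each way with the largest fold change per treatment contrast and up to 3 each way per line difference, among those called with both treated values on the same side of both vehicle values. It names up to 4 members per list with the smallest p, and always CSK and LYN. Features without a symbol, XIST and Y-linked genes were passed over, and some list members are not reported here. Alternatives were other filters, thresholds, scalings, variance models, sets of libraries, a replicate block, list tests with an estimated correlation or by fry, and leaving out each library. Fits without 1 library kept all others, so those of DOHH2 at 1, 3 and 6 h kept the 24 h libraries and their spread. Alternatives chosen after the data were seen were voom on recovered reads, scaling to total mapped reads, leaving out the DOHH2 24 h libraries, the crossed pairing of those libraries, a GC content and length correction, and list tests under other scalings and without the DOHH2 24 h libraries (adjusted over 78 tests). The planned quasi-likelihood count test was not run, since the table was not given as counts, though the recovered reads used for voom could have served it. The limma steps were tested on simulated data with 12000 genes and 50 changed genes per fold. In TMD8 at 6 h they recovered 52, 76, 86 and 100% at folds of 1.25, 1.5, 2 and 4, with 10 false calls. In DOHH2 at 6 h they recovered 36, 74, 82 and 96%, with 9 false calls. The simulation gave all groups of a line the same spread per gene, from the fit with the 24 h libraries. It thus does not cover groups of unequal spread, as found in DOHH2.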

Results

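RNA of 2 human diffuse large B-cell lymphoma (DLBCL) cell lines was sequenced after treatment with CSKi, an inhibitor of the C-terminal Src kinase CSK, or with the vehicle DMSO. CSK phosphorylates the inhibitory tyrosine in the tail of Src family kinases, and LYN is the main Src family kinase of B cells. TMD8 is a line of the activated B cell type and DOHH2 a line of the germinal centre B cell type, and the labels describe both as carrying an engineered Cas9. Each line received 500 nM CSKi or DMSO for 1, 3, 6 and 24 h in duplicate, which gave 16 groups of 2 libraries and 32 libraries in all. Libraries held 12273442 to 24907030 mapped reads. Of the 12000 features tested in each line, the one with the lowest mean had 20.6 reads per library in TMD8 and 14.5 reads in DOHH2. The comparisons ask which transcripts differ after CSK inhibition at each time, and whether both lines respond alike.

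Duplicates of a group correlated across features with r from 0.994 to 0.997 in 14 of the 16 groups. The 2 DOHH2 groups at 24 h stood apart, with r = 0.990 for DMSO and r = 0.987 for CSKi. There, the library labelled DMSO replicate 1 lay closer to the library labelled CSKi replicate 2 (SD of the log2 difference over features 0.218) than to its own duplicate (0.328). The library labelled DMSO replicate 2 lay closer to CSKi replicate 1 (0.275), and the 2 CSKi libraries differed from each other by 0.381. Every DOHH2 value at 24 h is given with this limit.

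In vehicle, the lines differed in the genes that define their DLBCL types. Of 17 activated B cell type genes tested, 16 were higher in TMD8 (median log2 difference 3.13). They included the phosphatase gene PTPN1 (3.32 ± 0.02), the kinase-binding protein gene SH3BP5 (3.27 ± 0.03) and BATF (5.63 ± 0.06), a B cell transcription factor (± SE of the fit throughout, n = 8 vehicle libraries per line here). Of 18 germinal centre B cell genes, 12 were higher in DOHH2 and 6 in TMD8 (median -1.495). The sphingosine phosphate receptor gene S1PR2 (-4.54 ± 0.07) and GCSAM (GCET2 in the table, -8.98 ± 0.15) were higher in DOHH2, and the transcription factor gene SPIB was higher in TMD8 (3.35 ± 0.04). MME, which encodes the surface peptidase CD10, had a mean log2 value of 12.9 in DOHH2 and 0.43 in TMD8. Of 21 NF-kB target genes, 20 were higher in TMD8 (median 2.09). In all, 10697 of 12000 features differed between the lines in vehicle by limma, 5118 higher in TMD8 and 5579 higher in DOHH2, and 6227 of them differed at least 1.5-fold.

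Both lines also changed over the 24 h in vehicle alone. In TMD8, all 17 glycolysis and hypoxia genes tested were higher in vehicle at 24 h than at 1 h, with the hexokinase gene HK2 at 1.05 ± 0.04, the lactate dehydrogenase gene LDHA at 0.84 ± 0.04 and the enolase gene ENO2 at 2.05 ± 0.10 on the log2 scale (n = 2 and 2). All 20 G2/M genes were higher as well (median 0.55), such as the proliferation marker MKI67 (0.60 ± 0.04). In turn, 18 of 22 interferon response genes were lower (ISG15, -0.96 ± 0.07) and 11 of 12 MHC class II genes were lower (CD74, -0.58 ± 0.03). In DOHH2, 21 of 23 cholesterol and fatty acid synthesis genes were lower at 24 h, including HMGCS1 (-1.70 ± 0.07) and LSS (-1.14 ± 0.05). These DOHH2 values carry the limit above, since each library labelled DMSO at 24 h lay closer to a CSKi library than to its duplicate. They may therefore not be change in vehicle alone. Over all 4 times, 7006 features changed in TMD8 vehicle and 3518 in DOHH2 vehicle. In DOHH2, the F test over 1, 3 and 6 h alone, without the 24 h libraries, called 6338. Without single DOHH2 vehicle libraries of the 1, 3 or 6 h groups the count was 1878 to 2312.

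**Figure D1:**
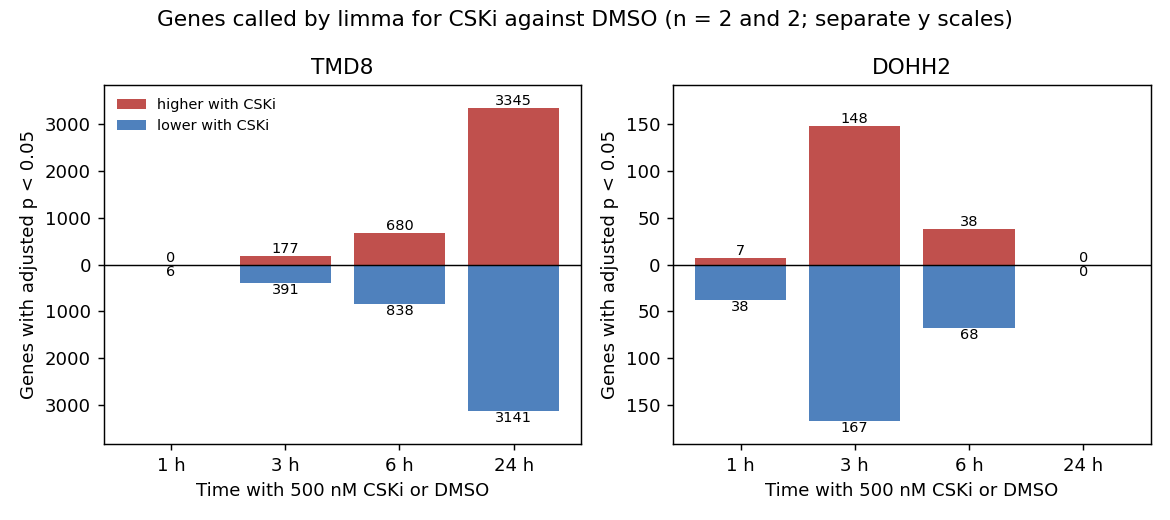
Number of genes called by limma for CSKi against DMSO (adjusted p under 0.05, n = 2 and 2 libraries) by time in h, higher in red above 0 and lower in blue below 0, with separate y scales for TMD8 and DOHH2. Calls in TMD8 go from 6 at 1 h to 6486 at 24 h, and in DOHH2 from 45 at 1 h to 315 at 3 h, 106 at 6 h and 0 at 24 h, where 378 had an unadjusted p under 0.05. The labels of the DOHH2 libraries at 24 h are in doubt, and their spread enters all DOHH2 counts shown. Without them 99 rose and 145 fell at 1 h, 874 and 873 at 3 h, and 836 and 801 at 6 h.

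In TMD8, transcripts of immediate early transcription factors and of TNF were lower within 1 h of CSKi. EGR2 (Gene ID 1959), a zinc finger transcription factor induced early after receptor signalling, fell 4.06-fold (log2 -2.02 ± 0.17, n = 2 and 2). The cytokine gene TNF (Gene ID 7124) fell 3.70-fold (-1.89 ± 0.12), and EGR1 (Gene ID 1958) fell 2.38-fold (-1.25 ± 0.16). DUSP2 (Gene ID 1844), a phosphatase of ERK, fell 1.81-fold (-0.86 ± 0.10), and ZFP36L1 (Gene ID 677), which promotes decay of AU-rich transcripts, fell 1.22-fold (-0.28 ± 0.05). With the antisense transcript ARHGAP44-AS1 (LOC100128006 in the table, -0.75, named after its value was seen), these were the 6 genes called of 12000 tested, all of them lower. In vehicle, EGR2 stood 1.12 ± 0.17 and EGR1 1.48 ± 0.16 higher at 1 h than at 6 h. The call of ZFP36L1 was lost without any 1 of the 4 libraries compared (adjusted p up to 0.356).

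Among the fixed lists at 1 h, 2 of 21 immediate early genes fell in TMD8, EGR2 and EGR1, and 8 fell adjusted over the list alone (camera adjusted p = 2.75e-10, and adjusted p = 0.0081 with an estimated correlation). EGR3 stood at -0.98 ± 0.22 (adjusted p = 0.209). Of 26 NF-kB target genes 1 fell, TNF, and 4 fell adjusted over the list alone (camera adjusted p = 0.00247, but adjusted p = 0.111 with an estimated correlation). Of 10 cytokine and chemokine genes 1 fell, again TNF, and adjusted over the list alone 2 fell and 1 rose (camera adjusted p = 0.00187, but adjusted p = 0.059 with an estimated correlation). The lists of heat shock genes (median 0.07), germinal centre genes (median 0.04) and actin and adhesion genes (median 0.04) were shifted upward with no member called, in all genes or adjusted over the list alone. Their camera adjusted p were 0.00174, 0.0302 and 0.0153, and none held (adjusted p = 0.274, 0.158 and 0.331 with an estimated correlation). The actin list was also not called after quantile normalization (adjusted p = 0.126).

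At 3 h in TMD8, the same early genes were lower still. EGR2 fell 22.7-fold (-4.51 ± 0.17, n = 2 and 2), TNF 6.51-fold (-2.70 ± 0.12) and EGR1 5.16-fold (-2.37 ± 0.16). The growth factor gene HBEGF (Gene ID 1839) fell 8-fold (-3.00 ± 0.36, from 21 and 24 reads to 2 and 5), and IL10 (Gene ID 3586), an anti-inflammatory cytokine, fell 7.14-fold (-2.84 ± 0.15). The largest rises were smaller, in OSR2 (Gene ID 116039), a zinc finger transcription factor (1.84-fold, 0.88 ± 0.17), and ZNF860 (Gene ID 344787, 1.77-fold, 0.82 ± 0.22). They were followed by the orphan receptor gene GPR146 (Gene ID 115330, 1.74-fold, 0.80 ± 0.17), LRRC37B (Gene ID 114659, 1.71-fold, 0.77 ± 0.20) and the homeobox gene HOXC6 (Gene ID 3223, 1.71-fold, 0.77 ± 0.19). CSK itself fell 1.10-fold (-0.14 ± 0.04, adjusted p = 0.0216). In all, 177 genes rose and 391 fell, and 17 rose and 71 fell by at least 1.5-fold. Without any 1 of the 4 libraries compared the total was 256 to 315. The calls of CSK and of the 5 named genes that rose were each lost without at least 1 of them (adjusted p up to 0.419, for LRRC37B), and the value of HBEGF ranged from -3.64 to -2.36.

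Lists of signalling targets were lower at 3 h in TMD8. Of 21 immediate early genes 10 fell, including MYC (-0.86 ± 0.06) and the nuclear receptor gene NR4A3 (-1.18 ± 0.13), and adjusted over the list alone 14 fell and 1 rose (camera adjusted p = 5.22e-16, and adjusted p = 0.00377 with an estimated correlation). Of 7 ERK feedback genes 4 fell, DUSP2 (-2.01 ± 0.10), SPRED2 (-0.65 ± 0.09), SPRED1 (-0.70 ± 0.13) and PHLDA1 (-0.29 ± 0.08), and 6 fell adjusted over the list alone (camera adjusted p = 5.48e-10, and adjusted p = 0.00724 with an estimated correlation). Of 26 NF-kB target genes 14 fell and 1 rose, and adjusted over the list alone 16 fell and 2 rose (camera adjusted p = 1.17e-16, and adjusted p = 0.00298 with an estimated correlation). Members included CD83, a B cell activation marker, at -1.31 ± 0.05 and the survival gene BCL2A1 at -0.67 ± 0.05. Of 10 cytokine and chemokine genes 6 fell, also adjusted over the list alone (camera adjusted p = 1.52e-15, and adjusted p = 0.00296 with an estimated correlation). Among them were lymphotoxin LTA at -1.30 ± 0.16 and IL16 at -0.33 ± 0.04. Of 11 B cell activation markers 5 fell and 2 rose, and adjusted over the list alone 7 fell and 2 rose (camera adjusted p = 6.23e-07, and adjusted p = 0.00908 with an estimated correlation). These included CD69 at -2.09 ± 0.27, NFATC1 at -0.59 ± 0.07 and the costimulator CD80 at 0.38 ± 0.07.

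Lists of MYC and ribosome biogenesis, unfolded protein response and plasma cell differentiation genes were also lower at 3 h in TMD8. Of 26 MYC and ribosome biogenesis genes 12 fell, and 17 fell adjusted over the list alone (camera adjusted p = 1.67e-14, and adjusted p = 0.0259 with an estimated correlation). Members included the polyamine enzyme gene ODC1 at -0.26 ± 0.04 and RRS1 at -0.40 ± 0.06. Of 14 unfolded protein response genes 4 fell, also adjusted over the list alone, including the chaperone HSPA5 (-0.26 ± 0.03) and XBP1 (-0.34 ± 0.08; camera adjusted p = 0.000227, and adjusted p = 0.0259 with an estimated correlation). Of 11 plasma cell differentiation genes 3 fell, PRDM1 (-0.33 ± 0.05), XBP1 (-0.34 ± 0.08) and FKBP11 (-0.25 ± 0.07), and 4 fell adjusted over the list alone (camera adjusted p = 0.000661, and adjusted p = 0.0379 with an estimated correlation).

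A further 8 lists at 3 h in TMD8 were called by camera but not with an estimated correlation. B cell receptor pathway components were lower, with 5 of 25 fallen and 1 risen, and 6 and 1 adjusted over the list alone (camera adjusted p = 0.000917, but adjusted p = 0.254 with an estimated correlation). They included the phosphatase PTPN6 (-0.75 ± 0.03) and the inhibitory receptor CD72 (-0.51 ± 0.04). Cholesterol and fatty acid synthesis genes were lower (camera adjusted p = 3.35e-05, but adjusted p = 0.245 with an estimated correlation). Of 21 tested 4 fell, and 5 adjusted over the list alone. Germinal centre genes were lower, with 3 of 14 fallen, LMO2 (-0.77 ± 0.06), SPIB (-0.53 ± 0.04) and RGS13 (-0.32 ± 0.09), and 4 fallen and 1 risen adjusted over the list alone (camera adjusted p = 0.00626, but adjusted p = 0.0891 with an estimated correlation). MHC class II genes were lower, with 1 of 12 fallen, their transactivator CIITA (-0.59 ± 0.07), and 2 adjusted over the list alone (camera adjusted p = 0.00701, but adjusted p = 0.158 with an estimated correlation). Actin and adhesion genes were lower, with 3 of 17 fallen and 5 adjusted over the list alone (camera adjusted p = 0.00559, but adjusted p = 0.274 with an estimated correlation). Heat shock genes were lower too, with 1 of 9 fallen only adjusted over the list alone (camera adjusted p = 0.0128, but adjusted p = 0.352 with an estimated correlation). G2/M genes were higher, with 4 of 20 risen, TOP2A (0.22 ± 0.04), CENPF, KIF20A and TTK, and 8 adjusted over the list alone (camera adjusted p = 2.87e-06, but adjusted p = 0.147 with an estimated correlation). Interferon response genes were higher, with 4 of 22 risen, OAS1 (0.37 ± 0.05), OAS2 and STAT2 among them, and 8 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.000612, but adjusted p = 0.352 with an estimated correlation).

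**Figure D2:**
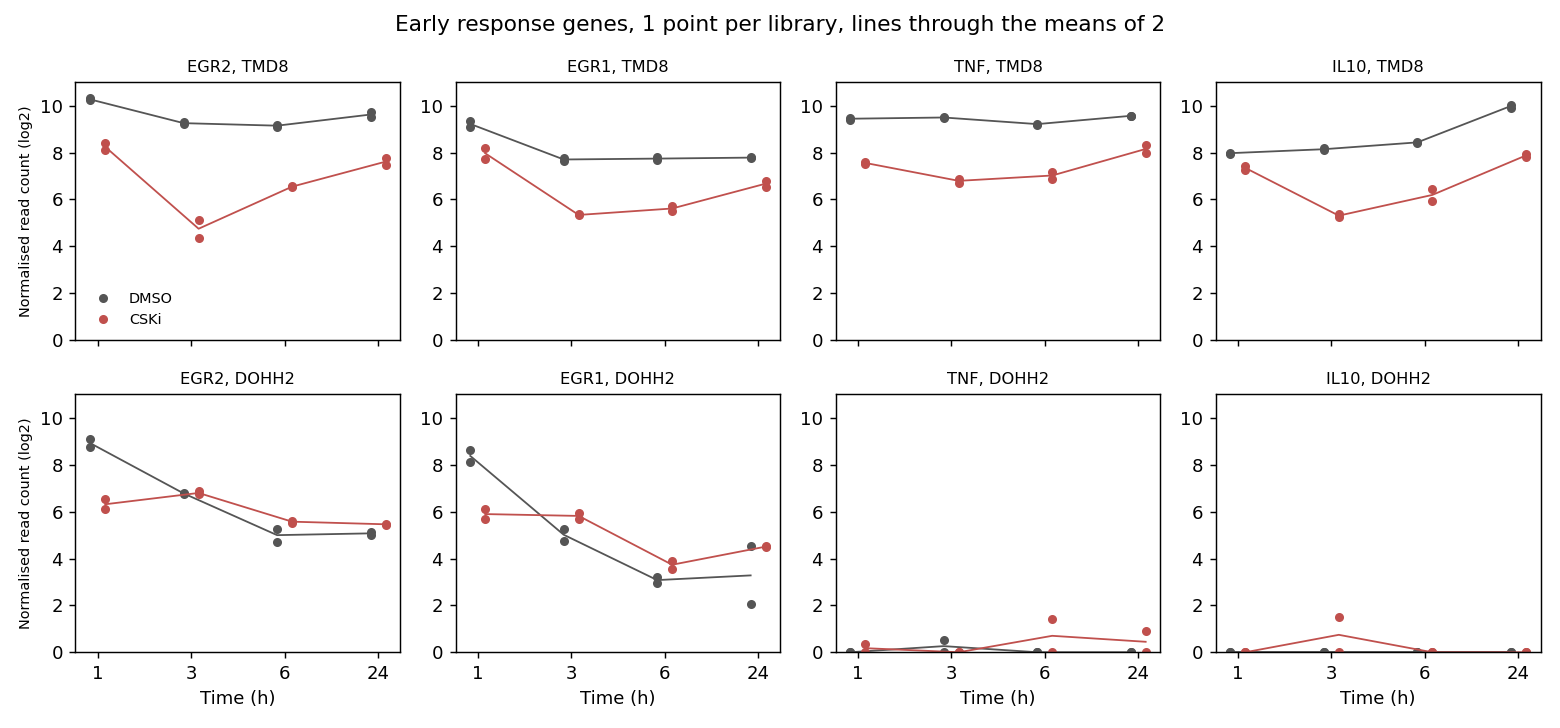
Normalised read count on a log2 scale for EGR2, EGR1, TNF and IL10 in TMD8 (upper panels) and DOHH2 (lower panels) by time in h, with 1 point per library and lines through the means of 2. In TMD8 the CSKi libraries lie under the DMSO libraries for these 4 genes at each time, and in DOHH2 those of EGR2 and EGR1 do so at 1 h, while TNF and IL10 lie near 0 reads there.

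At 6 h in TMD8, EGR2 (-2.60 ± 0.17, 6.07-fold lower, n = 2 and 2), IL10 (-2.24 ± 0.15, 4.73-fold) and TNF (-2.19 ± 0.12, 4.57-fold) were still lower. The ETS transcription factor gene ETV5 (Gene ID 2119) fell 4.50-fold (-2.17 ± 0.34) from 41 and 33 reads to 12 and 5, and the protease gene ASTL (Gene ID 431705) fell 5.75-fold (-2.52 ± 0.33) from 38 and 34 reads to 5 and 7. The secreted phospholipase gene PLA2G2D (Gene ID 26279) rose 2.31-fold (1.21 ± 0.26), the phosphatase gene CDC14B (Gene ID 8555) 2.12-fold (1.08 ± 0.30) and the extracellular matrix protein gene LTBP2 (Gene ID 4053) 2.05-fold (1.04 ± 0.24). The endocytic adaptor gene PACSIN1 (Gene ID 29993) rose 2.02-fold (1.01 ± 0.16) and the chromatin remodelling gene CECR2 (Gene ID 27443) 2.02-fold (1.01 ± 0.17). LYN fell 1.10-fold (-0.14 ± 0.04, adjusted p = 0.0108). In all, 680 genes rose and 838 fell, and 62 rose and 120 fell by at least 1.5-fold. Without any 1 of the 4 libraries compared the total was 836 to 890. The calls of PLA2G2D, CDC14B, LTBP2 and LYN were each lost without at least 1 of them (adjusted p up to 0.224, for LYN), and the value of ETV5 ranged from -2.89 to -1.45.

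At 6 h in TMD8, 23 of 26 MYC and ribosome biogenesis genes fell, and 24 adjusted over the list alone (camera adjusted p = 1.64e-27, and adjusted p = 0.00803 with an estimated correlation). These included ODC1 at -0.44 ± 0.04 and the transferrin receptor TFRC at -0.38 ± 0.04. Of 21 cholesterol and fatty acid synthesis genes 13 fell, and 17 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.27e-14, and adjusted p = 0.0329 with an estimated correlation). Members included FASN at -0.42 ± 0.04 and HMGCS1 at -0.50 ± 0.06. Of 12 MHC class II genes 5 fell and 7 adjusted over the list alone (camera adjusted p = 1.01e-06, and adjusted p = 0.0223 with an estimated correlation). Among them were CIITA at -0.90 ± 0.07 and HLA-DMB at -0.42 ± 0.07. Of 14 unfolded protein response genes 5 fell, and 10 adjusted over the list alone (camera adjusted p = 2.32e-07, and adjusted p = 0.0081 with an estimated correlation). The list held HSPA5 at -0.40 ± 0.03. Of 21 immediate early genes 8 fell and 1 rose, 12 and 2 adjusted over the list alone (camera adjusted p = 3.23e-06, and adjusted p = 0.0259 with an estimated correlation). Of 7 ERK feedback genes 6 fell, among them DUSP2 (-1.68 ± 0.10) and SPRED1 (-1.03 ± 0.13), and adjusted over the list alone 6 fell and 1 rose (camera adjusted p = 3.12e-07, and adjusted p = 0.00954 with an estimated correlation). Of 26 NF-kB target genes 10 fell and 2 rose, 16 and 2 adjusted over the list alone (camera adjusted p = 1.95e-10, and adjusted p = 0.00803 with an estimated correlation). Members included CD83 at -1.20 ± 0.05 and the chemokine receptor CCR7 at 0.63 ± 0.06. Of 10 cytokine and chemokine genes 5 fell, also adjusted over the list alone, with IL6 at -1.97 ± 0.25 (camera adjusted p = 2.32e-07, and adjusted p = 0.0081 with an estimated correlation).

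A further 5 lists at 6 h in TMD8 were called by camera but not with an estimated correlation. B cell activation markers were lower, with 3 of 11 fallen and 2 risen, 6 and 2 adjusted over the list alone (camera adjusted p = 0.00417, but adjusted p = 0.0809 with an estimated correlation). Actin and adhesion genes were lower, with 3 of 17 fallen and 2 risen, 6 and 2 adjusted over the list alone, including the integrin ITGA4 (-0.56 ± 0.06; camera adjusted p = 0.0386, but adjusted p = 0.381 with an estimated correlation and 0.0592 after quantile normalization). G2/M genes were higher, with 9 of 20 risen and 13 adjusted over the list alone (camera adjusted p = 1.87e-06, but adjusted p = 0.145 with an estimated correlation). The list held TOP2A at 0.27 ± 0.04. Ribosomal protein genes were higher, with 2 of 31 risen and none adjusted over the list alone (camera adjusted p = 0.00162, but adjusted p = 0.674 with an estimated correlation). Replication dependent histone genes were higher, with 2 of 8 risen, HIST1H2BD (0.38 ± 0.06) and HIST1H2AC (0.31 ± 0.07), and 3 adjusted over the list alone (camera adjusted p = 0.00681, but adjusted p = 0.136 with an estimated correlation).

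At 24 h in TMD8, 3345 genes rose and 3141 fell, of which 1006 rose and 479 fell by at least 1.5-fold. The adhesion gene IGSF11 (Gene ID 152404) fell 12-fold (-3.58 ± 0.27, n = 2 and 2, from 57 and 99 reads to 5 and 5). CXCL13 (Gene ID 10563), a chemokine that attracts B cells, fell 7.97-fold (-2.99 ± 0.24), the calcium channel gene CACNA1D (Gene ID 776) 7.21-fold (-2.85 ± 0.31), the ectonucleotidase gene ENPP1 (Gene ID 5167) 6.41-fold (-2.68 ± 0.14) and IL10 4.33-fold (-2.11 ± 0.15). In vehicle IL10 stood 2.01 ± 0.15 higher at 24 h than at 1 h. Its log2 values were 7.827 and 7.924 with CSKi at 24 h and 7.956 and 7.999 in vehicle at 1 h. HRK (Gene ID 8739), a pro-apoptotic BH3-only member of the BCL2 family, rose 3.85-fold (1.95 ± 0.23), and the monocarboxylate transporter gene SLC16A8 (Gene ID 23539) 4.09-fold (2.03 ± 0.34). The complexin gene CPLX1 (Gene ID 10815) rose 3.87-fold (1.95 ± 0.16) and the scavenger receptor gene SCARF1 (Gene ID 8578) 3.63-fold (1.86 ± 0.33). The small nucleolar RNA SNORD3A (Gene ID 780851) had the highest fold among genes that rose, 7.08 (2.82 ± 0.86), but its vehicle libraries held 1 and 30 reads, and without vehicle replicate 1 it was not called (0.64, adjusted p = 0.504). The other 9 named genes were called without any 1 of the 4 libraries.

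Cell cycle and growth genes were lower with CSKi than in vehicle at 24 h in TMD8. In vehicle itself, all 20 G2/M genes rose from 1 to 24 h (median 0.552). Of 21 G1/S genes 18 rose and 2 fell there (median 0.25), and of 9 heat shock genes 8 rose. Of 26 MYC and ribosome biogenesis genes 11 rose and 3 fell, and of 8 STAT3 and SOCS genes 6 rose and 1 fell. The falls given here are against vehicle at 24 h and need not lie under the level at 1 h. Of 21 G1/S genes 20 fell, also adjusted over the list alone (camera adjusted p = 2.48e-13, and adjusted p = 0.00954 with an estimated correlation). These included the ribonucleotide reductase subunit RRM2 at -0.73 ± 0.04, the replication clamp PCNA at -0.66 ± 0.04 and the helicase subunit MCM4 at -0.62 ± 0.04. All 26 MYC and ribosome biogenesis genes fell, also adjusted over the list alone (camera adjusted p = 1.75e-16, and adjusted p = 0.0223 with an estimated correlation). Members included TFRC at -0.84 ± 0.04 and nucleolin NCL at -0.57 ± 0.03. All 20 G2/M genes fell, also adjusted over the list alone (camera adjusted p = 6.5e-08, but adjusted p = 0.101 with an estimated correlation). Among them were CCNB1 at -0.42 ± 0.04 and UBE2C at -0.45 ± 0.04. Of 9 heat shock genes 8 fell, also adjusted over the list alone, with HSPA8 at -0.79 ± 0.04 (camera adjusted p = 1.46e-05, but adjusted p = 0.136 with an estimated correlation). Of 8 STAT3 and SOCS genes 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0381, but adjusted p = 0.457 with an estimated correlation and 0.0606 after quantile normalization). These included SOCS3 at -1.88 ± 0.07, STAT3 at -0.96 ± 0.04 and the kinase gene PIM2 at 0.52 ± 0.04.

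Further lists at 24 h in TMD8 were higher by camera but not called with an estimated correlation, among them B cell receptor pathway components and interferon response genes. From 1 to 24 h in vehicle itself, 18 of 22 interferon response and 6 of 8 histone genes fell, and none rose. Of 25 B cell receptor pathway components 12 fell and 6 rose there. Of 16 FOXO target genes 6 fell and 3 rose, and of 31 ribosomal protein genes 17 fell and 3 rose. Src family kinases and regulators went both ways (6 rose, 4 fell), and all 17 glycolysis and hypoxia genes rose. The rises given here are against vehicle at 24 h and need not lie over the level at 1 h. Of 25 B cell receptor pathway components 17 rose and 1 fell, 17 and 2 adjusted over the list alone (camera adjusted p = 9.4e-06, but adjusted p = 0.136 with an estimated correlation). Members included the receptor chain CD79B at 0.89 ± 0.04, VAV2 at 0.67 ± 0.04 and the adaptor BLNK at 0.59 ± 0.04. Of 15 Src family kinases and regulators 6 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0428, but adjusted p = 0.19 with an estimated correlation and 0.107 after quantile normalization). Among them were the phosphatase PTPRC at 0.48 ± 0.03, the ubiquitin ligase CBLB at 0.84 ± 0.06 and PAG1, the membrane anchor of CSK, at 0.60 ± 0.08. Of 16 FOXO target genes 10 rose and 1 fell, 12 and 1 adjusted over the list alone (camera adjusted p = 0.00218, but adjusted p = 0.145 with an estimated correlation). These included BCL2L11 at 0.59 ± 0.03 and TXNIP at 0.78 ± 0.06. In vehicle they stood at -0.25 ± 0.03 and -0.77 ± 0.06 at 24 h against 1 h. Of 22 interferon response genes 16 rose, 17 adjusted over the list alone (camera adjusted p = 2.39e-05, but adjusted p = 0.274 with an estimated correlation). Members included OAS1 at 1.37 ± 0.05 and IFIT2 at 1.21 ± 0.11. Of 17 glycolysis and hypoxia genes 13 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00158, but adjusted p = 0.566 with an estimated correlation). Among them were ALDOC at 1.502 ± 0.13, VEGFA at 0.77 ± 0.09 and LDHA at -0.29 ± 0.04. Of 31 ribosomal protein genes 30 rose, also adjusted over the list alone (camera adjusted p = 2.14e-11, but adjusted p = 0.343 with an estimated correlation). These included RPL15 at 0.31 ± 0.03. After quantile normalization 17 of them rose and 3 fell, and the median went from 0.242 to 0.078 (camera adjusted p = 0.00648). Of 8 replication dependent histone genes 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0236, but adjusted p = 0.194 with an estimated correlation). Members included HIST1H2BD at 0.84 ± 0.06.

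The early signalling lists were not called at 24 h in TMD8, though many of their members were. Of 21 immediate early genes 5 rose and 10 fell, also adjusted over the list alone (median -0.17, camera adjusted p = 0.421), with EGR2 at -2.01 ± 0.17, EGR1 at -1.11 ± 0.16 and MYC at -0.77 ± 0.06. Of 7 ERK feedback genes 1 rose and 4 fell, also adjusted over the list alone (median -0.94, camera adjusted p = 0.162), with PHLDA1 at -1.25 ± 0.08 and DUSP2 at -1.20 ± 0.10. Of 26 NF-kB target genes 8 rose and 13 fell, also adjusted over the list alone (median -0.24, camera adjusted p = 0.0614), and of 10 cytokine and chemokine genes 3 rose and 4 fell, also adjusted over the list alone (median -0.16, camera adjusted p = 0.761). These held TNF at -1.41 ± 0.12, IL6 at -2.07 ± 0.25 and IL16 at 0.66 ± 0.04. Of 11 B cell activation markers 3 rose and 4 fell, also adjusted over the list alone (median -0.07, camera adjusted p = 0.759), with CD83 at -0.65 ± 0.05 and CD69 at -0.80 ± 0.27.

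Other lists at 24 h in TMD8 also held called members and were not called as lists. Rises and falls of these members are also against vehicle at 24 h, which itself changed from 1 h. Of 14 unfolded protein response genes 3 rose and 8 fell, of 11 plasma cell differentiation genes 5 rose and 4 fell, and of 17 actin and adhesion genes 4 rose and 5 fell, each also adjusted over the list alone (camera adjusted p = 0.133, 0.617 and 0.949). Of 14 germinal centre genes 6 rose and 5 fell, 7 and 6 adjusted over the list alone, and of 12 MHC class II genes 5 rose, 4 adjusted over the list alone (camera adjusted p = 0.958 and 0.214). Of 14 BCL2 family genes 7 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.214). Among them were the pro-apoptotic BMF at 1.45 ± 0.06 and BCL2L11 at 0.59 ± 0.03, BCL2 at 0.55 ± 0.04 and BID at -0.59 ± 0.05. Of 18 p53 target genes 9 rose and 2 fell, also adjusted over the list alone, with BTG2 at 0.74 ± 0.03 and BBC3 at 0.66 ± 0.10 (camera adjusted p = 0.0774). Of 17 activated B cell type genes 7 rose and 5 fell, 8 and 5 adjusted over the list alone (camera adjusted p = 0.336). These included IRF4 at -0.52 ± 0.03 and BATF at -1.09 ± 0.06. Of 21 cholesterol and fatty acid synthesis genes 11 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0514, and 0.0207 after quantile normalization). The list held LSS at 0.86 ± 0.05. Of 13 B cell migration genes 5 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.94, with a median of -0.09 and a mean of 0.06). Among them were CCR7 at 1.34 ± 0.06, CXCR4 at 0.94 ± 0.08 and RGS13 at -1.29 ± 0.09. Of 20 ATF4 and amino acid response genes 6 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.868, with a median of -0.03 and a mean of 0.08). These included ATF5 at 0.87 ± 0.07 and ASNS at -0.80 ± 0.07.

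**Figure D3:**
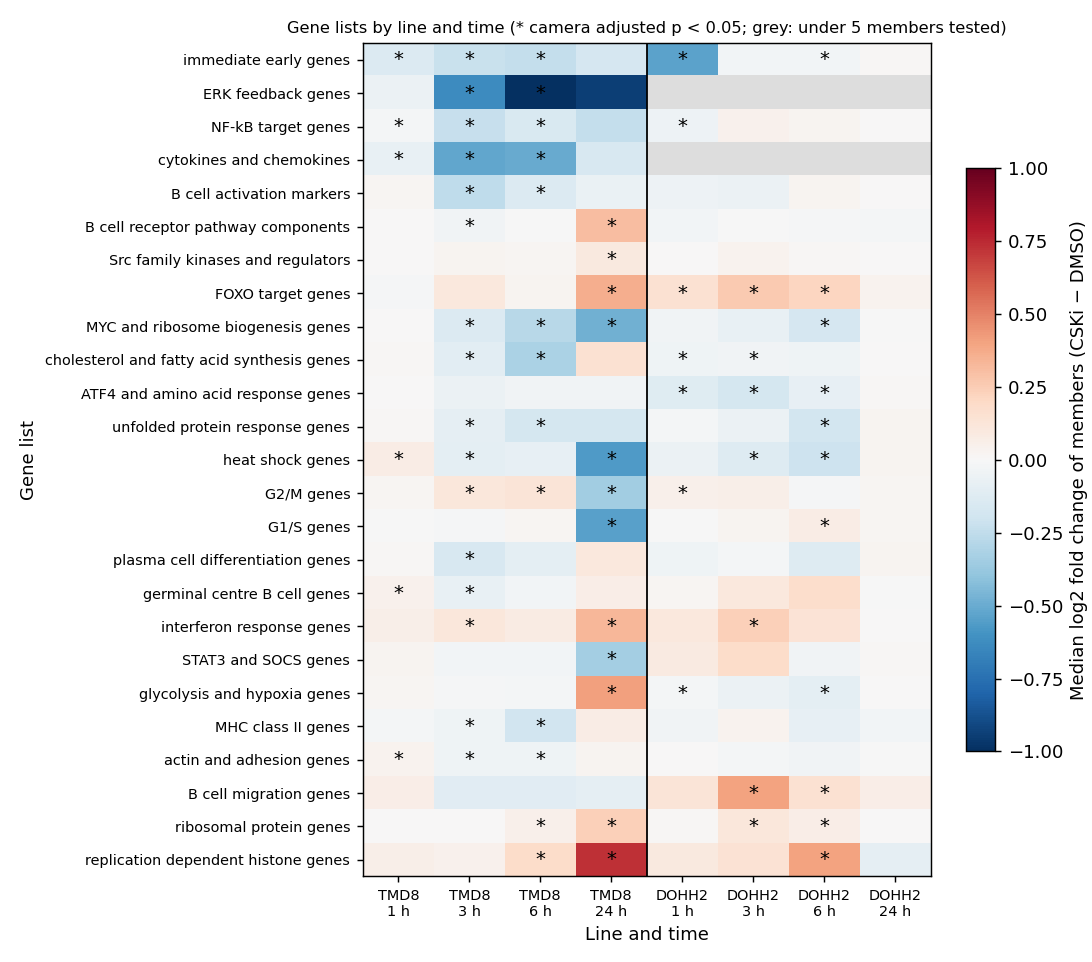
Median log2 fold change (CSKi minus DMSO) of the tested members of each gene list (y axis) by line and time (x axis), on a colour scale from -1 to 1, with an asterisk where camera gave an adjusted p under 0.05 and grey where fewer than 5 members were tested. In TMD8 the early signalling lists are lower at 3 and 6 h and the cell cycle lists at 24 h, and in DOHH2 the immediate early list is lower at 1 h (median -0.53).

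The TMD8 response was carried from one time to the next in part. Of the genes called at 3 and 6 h, 114 were higher and 298 lower at both, where 10.0 and 27.3 would be shared by independent lists (two-sided Fisher exact p = 1.84e-99 and 6.34e-280, over genes, which are not independent replicates). At 6 and 24 h, 527 were higher and 553 lower at both (190 and 219 for independent lists), and 145 were called in opposite directions. No vehicle library is shared between these contrasts. The size of the response changed over time for 4727 genes in TMD8 (limma F test), and 1458 of these also changed at least 1.5-fold.

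In DOHH2, the immediate early genes were lower at 1 h. EGR2 fell 6.10-fold (-2.61 ± 0.21, n = 2 and 2) and the nuclear receptor gene NR4A1 (Gene ID 3164) fell 4.05-fold (-2.02 ± 0.15). In vehicle, EGR2 went from log2 values of 8.756 and 9.09 at 1 h to 4.719 and 5.275 at 6 h. EGR1 went there from 8.122 and 8.636 to 3.205 and 2.953. Whether CSKi only held back an induction in vehicle at 1 h was not tested in DOHH2 and stays open. ZFP36L1 fell 2.23-fold (-1.16 ± 0.05), the G protein regulator gene RGS2 (Gene ID 5997) 2.21-fold (-1.15 ± 0.10) and the pseudogene BMS1P1 (Gene ID 399761, BMS1P5 in the table) 3.16-fold (-1.66 ± 0.31, from 49 and 39 reads to 17 and 9). The GTPase activating protein gene TAGAP (Gene ID 117289) rose 2.53-fold (1.34 ± 0.20) and the actin-binding protein gene SYNPO2 (Gene ID 171024) 2.01-fold (1.00 ± 0.19). The ubiquitin ligase gene MYLIP (Gene ID 29116) rose 1.60-fold (0.68 ± 0.12), TIFA (Gene ID 92610), an adaptor of NF-kB signalling, 1.59-fold (0.67 ± 0.12) and TXNIP (Gene ID 10628), an inhibitor of glucose uptake, 1.5-fold (0.59 ± 0.09). In all, 7 genes rose and 38 fell. Without the 24 h libraries, whose spread enters the fit of this line, 99 rose and 145 fell, the 10 named genes among them. Fits that left out 1 library of this time kept the 24 h libraries and their spread. In them values ranged from 1.29 to 1.39 for TAGAP, 0.98 to 1.02 for SYNPO2 and 0.57 to 0.79 for MYLIP. They ranged from 0.64 to 0.71 for TIFA, 0.53 to 0.64 for TXNIP and -1.81 to -1.50 for BMS1P1. Without any 1 of the 4 libraries compared the total was 13 to 16. The calls of TAGAP, SYNPO2, MYLIP, TIFA, TXNIP and BMS1P1 were lost without at least 3 of them (adjusted p up to 0.457, for BMS1P1).

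At 1 h in DOHH2, 7 of 19 immediate early genes fell and 12 adjusted over the list alone (camera adjusted p = 3.49e-26, and adjusted p = 0.00296 with an estimated correlation). Members included JUNB at -0.72 ± 0.07 and IER2 at -0.64 ± 0.08. The other lists called at 1 h were not called with an estimated correlation. Of 21 FOXO target genes 2 rose, TXNIP (0.59 ± 0.09) and CITED2 (0.54 ± 0.10), and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 1.01e-06, but adjusted p = 0.313 with an estimated correlation). Of 19 NF-kB target genes 2 fell, NFKBIE (-0.48 ± 0.06) and CD83 (-0.64 ± 0.10), and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.0026, but adjusted p = 0.498 with an estimated correlation). Of 14 glycolysis and hypoxia genes 1 fell, VEGFA (-0.35 ± 0.06), also adjusted over the list alone (camera adjusted p = 0.0426, but adjusted p = 0.674 with an estimated correlation and 0.0571 without the 24 h libraries). Cholesterol and fatty acid synthesis genes (median -0.04) and ATF4 and amino acid response genes (median -0.13) were lower and G2/M genes (median 0.05) higher as lists, with no member called, in all genes or adjusted over the list alone. Their camera adjusted p were 0.0228, 0.000794 and 0.0156 (adjusted p = 0.352, 0.469 and 0.457 with an estimated correlation). Without the 24 h libraries 12 immediate early genes fell, 6 FOXO target genes rose and 1 fell (adjusted p = 0.029 with an estimated correlation), and 5 NF-kB target genes fell and 1 rose. In that fit 3 ATF4 and amino acid response genes also fell, 1 G2/M gene rose, and the MYC and ribosome biogenesis list was called lower with 2 of 26 fallen (camera adjusted p = 0.0322, but adjusted p = 0.315 with an estimated correlation). Lists of ERK feedback genes and of cytokines were not tested in DOHH2, where 3 and 2 members passed the filter.

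At 3 h in DOHH2, EGR2 stood at the vehicle level (0.02, adjusted p over 0.9) and other genes led. The vehicle level of EGR2 itself was lower than at 1 h, with log2 values of 8.756 and 9.09 at 1 h, 6.786 and 6.77 at 3 h and 4.719 and 5.275 at 6 h, against 6.102 and 6.527, 6.86 and 6.735, and 5.613 and 5.531 with CSKi. The cadherin family gene CDHR3 (Gene ID 222256, FLJ23834 in the table) rose 2.89-fold (1.53 ± 0.14, n = 2 and 2) and the actin regulator gene WASF3 (Gene ID 10810) 2.83-fold (1.503 ± 0.34). Rises were also seen in C12orf42 (Gene ID 374470) 2.13-fold (1.09 ± 0.23), TBC1D9 (Gene ID 23158) 2.10-fold (1.07 ± 0.19) and the protease gene BACE2 (Gene ID 25825) 1.89-fold (0.92 ± 0.23). The formin gene INF2 (Gene ID 64423, C14orf151 in the table) fell 2.91-fold (-1.54 ± 0.33) from 25 and 25 reads to 9 and 7, and LRRN3 (Gene ID 54674) fell 2.84-fold (-1.504 ± 0.21). The forkhead gene FOXO6 (Gene ID 100132074) fell 2.40-fold (-1.27 ± 0.25), PLEKHH3 (Gene ID 79990) 2.11-fold (-1.08 ± 0.17) and NOL4L (Gene ID 140688, C20orf112 in the table) 2.09-fold (-1.06 ± 0.10). In all, 148 genes rose and 167 fell, and without the 24 h libraries 874 rose and 873 fell, the 10 named genes among them. Fits that left out 1 library of this time kept the 24 h libraries and their spread. Without any 1 of the 4 libraries compared the total was 30 to 87. Of the named genes the calls of CDHR3, LRRN3 and NOL4L were kept and those of the other 7 were each lost without at least 2 of them (adjusted p up to 0.377, for BACE2).

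At 6 h in DOHH2, GIMAP6 (Gene ID 474344), a GTPase of lymphocytes, rose 3.30-fold (1.72 ± 0.31, n = 2 and 2) and TP53INP1 (Gene ID 94241), a p53-inducible regulator of autophagy, 3.04-fold (1.61 ± 0.28). NLRP7 (Gene ID 199713) rose 2.26-fold (1.18 ± 0.17), CDHR3 (FLJ23834) 2.22-fold (1.153 ± 0.14) and the zinc finger gene ZNF608 (Gene ID 57507) 2.04-fold (1.03 ± 0.22). FOXO6 fell 2.44-fold (-1.29 ± 0.25), KIAA1671 (Gene ID 85379) 2.33-fold (-1.22 ± 0.14), the thrombin receptor gene F2RL3 (Gene ID 9002) 1.87-fold (-0.90 ± 0.18), the microtubule gene MAP1A (Gene ID 4130) 1.84-fold (-0.88 ± 0.13) and the ARF exchange factor gene IQSEC1 (Gene ID 9922) 1.84-fold (-0.88 ± 0.09). In all, 38 genes rose and 68 fell, and without the 24 h libraries 836 rose and 801 fell, the 10 named genes among them. Fits that left out 1 library of this time kept the 24 h libraries and their spread. Without any 1 of the 4 libraries compared the total was 9 to 34. Of the named genes the calls of CDHR3, KIAA1671 and IQSEC1 were kept and those of the other 7 were each lost without at least 3 of them (adjusted p up to 0.38, for F2RL3).

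Lists of FOXO targets, migration genes and ribosomal proteins were higher at 3 and 6 h in DOHH2, and lists of amino acid response and heat shock genes lower. Of 21 FOXO target genes 1 rose at 3 h, CITED2 (0.45 ± 0.10), with 8 risen and 2 fallen adjusted over the list alone (camera adjusted p = 0.000112, but adjusted p = 0.405 with an estimated correlation). At 6 h 2 of them rose, CITED2 (0.67 ± 0.10) and IL7R (0.29 ± 0.06), with 7 adjusted over the list alone (camera adjusted p = 4.43e-09, but adjusted p = 0.228 with an estimated correlation). Of 15 B cell migration genes 2 rose at 3 h, ITGA4 (0.40 ± 0.07) and RGS2 (0.52 ± 0.10), and 1 fell, P2RY8 (-0.26 ± 0.05), with 3 and 1 adjusted over the list alone (camera adjusted p = 0.00242, but adjusted p = 0.196 with an estimated correlation). At 6 h ITGA4 (0.47 ± 0.07) and RGS2 (0.52 ± 0.10) rose again, with 3 adjusted over the list alone (camera adjusted p = 0.0274, but adjusted p = 0.335 with an estimated correlation). Of 19 ATF4 and amino acid response genes 4 fell at 3 h and 5 adjusted over the list alone (camera adjusted p = 1.28e-05, but adjusted p = 0.346 with an estimated correlation). Among them were the amino acid transporter SLC7A5 at -0.44 ± 0.05 and PSAT1 at -0.36 ± 0.07. At 6 h SLC7A5 alone fell (-0.37 ± 0.05), also adjusted over the list alone (camera adjusted p = 0.0428, but adjusted p = 0.674 with an estimated correlation, 0.0542 after quantile normalization and 0.0571 without the 24 h libraries). Of 9 heat shock genes 2 fell at 3 h, DNAJB1 (-0.34 ± 0.06) and HSPA8 (-0.49 ± 0.09), with 3 adjusted over the list alone (camera adjusted p = 0.00221, but adjusted p = 0.393 with an estimated correlation). At 6 h the heat shock list was lower with no member called (median -0.21, camera adjusted p = 0.00417, but adjusted p = 0.431 with an estimated correlation). Ribosomal protein genes were higher as a list at 3 h (median 0.11, camera adjusted p = 2.35e-08, but adjusted p = 0.501 with an estimated correlation), with a median of 0.015 after quantile normalization (adjusted p = 0.0397). They were also higher at 6 h (median 0.07, camera adjusted p = 0.00114, but adjusted p = 0.745 with an estimated correlation and 0.103 after quantile normalization). At neither time was a member called, in all genes or adjusted over the list alone, but without the 24 h libraries 23 of 31 rose at 3 h and 6 at 6 h. In that fit 14 FOXO target genes rose and 2 fell at 3 h and 12 rose at 6 h (adjusted p = 0.0534 and 0.029 with an estimated correlation). Of the migration genes 8 rose and 1 fell at 3 h and 6 rose at 6 h (adjusted p = 0.029 and 0.0534 with an estimated correlation). Of the ATF4 and amino acid response genes 10 fell at 3 h, and 3 fell and 1 rose at 6 h, and of the heat shock genes 4 fell at 3 h and 5 at 6 h.

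Further lists in DOHH2 were called at 1 of these times. At 3 h, 2 of 23 cholesterol and fatty acid synthesis genes fell, SCD (-0.24 ± 0.05) and FASN (-0.30 ± 0.07), and 3 adjusted over the list alone (camera adjusted p = 0.00766, but adjusted p = 0.313 with an estimated correlation). Interferon response genes were higher at 3 h with no member called, also adjusted over the list alone (median 0.24, camera adjusted p = 0.000877, but adjusted p = 0.632 with an estimated correlation). At 6 h, G1/S genes were higher (median 0.08) with no member called, also adjusted over the list alone (camera adjusted p = 0.000289, and adjusted p = 0.0259 with an estimated correlation). At 6 h, 1 of 26 MYC and ribosome biogenesis genes fell, PPRC1 (-0.30 ± 0.06), and 12 adjusted over the list alone (camera adjusted p = 3.03e-12, but adjusted p = 0.274 with an estimated correlation). Of 19 immediate early genes 2 fell at 6 h, MYC (-0.34 ± 0.05) and KLF10 (-0.67 ± 0.12), and 5 adjusted over the list alone (camera adjusted p = 0.0383, but adjusted p = 0.335 with an estimated correlation and 0.0752 without the 24 h libraries). Unfolded protein response genes (median -0.19) were lower at 6 h, with 4 of 14 fallen and 1 risen only adjusted over the list alone (camera adjusted p = 0.000378, but adjusted p = 0.331 with an estimated correlation). Glycolysis and hypoxia genes (median -0.10) were lower, with 2 of 14 fallen only adjusted over the list alone (camera adjusted p = 0.0183, but adjusted p = 0.644 with an estimated correlation). Histone genes (median 0.40) were higher, with 1 of 5 risen only adjusted over the list alone (camera adjusted p = 0.0245, but adjusted p = 0.481 with an estimated correlation and 0.0752 without the 24 h libraries). In DOHH2 the lists of B cell activation markers, B cell receptor pathway components, Src family kinases and regulators, p53 targets, BCL2 family, plasma cell differentiation, germinal centre, activated B cell type, STAT3 and SOCS, MHC class II and actin and adhesion genes were not called at any time. Without the 24 h libraries, the germinal centre list was called higher at 6 h, with 9 of 18 risen and 3 fallen (camera adjusted p = 0.000624, but adjusted p = 0.0843 with an estimated correlation). In that fit 6 cholesterol and fatty acid synthesis genes fell and 2 interferon response genes rose at 3 h. At 6 h 19 MYC and ribosome biogenesis genes fell (adjusted p = 0.029 with an estimated correlation) and 7 G1/S genes rose (adjusted p = 0.0837 with an estimated correlation). Also at 6 h, 7 unfolded protein response genes fell and 1 rose, 6 immediate early genes fell and 1 rose, 4 glycolysis and hypoxia genes fell and 1 histone gene rose.

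At 24 h in DOHH2, limma called 0 genes for the libraries as labelled, with 378 at an unadjusted p under 0.05. Without the filter 7 genes were called, without the variance trend 1, and by voom on recovered reads 0. CSK stood at -0.02 ± 0.06 and LYN at 0.01 ± 0.09 (n = 2 and 2), and no list was called. On the 729 genes called the same way at 3 and 6 h without the 24 h libraries, the mean signed deviation from the line's mean was 0.04 for the library labelled DMSO replicate 1 and 0.03 for CSKi replicate 2, against -0.31 for DMSO replicate 2 and -0.27 for CSKi replicate 1. Without the library labelled CSKi replicate 2, 647 genes were called.

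**Figure D4:**
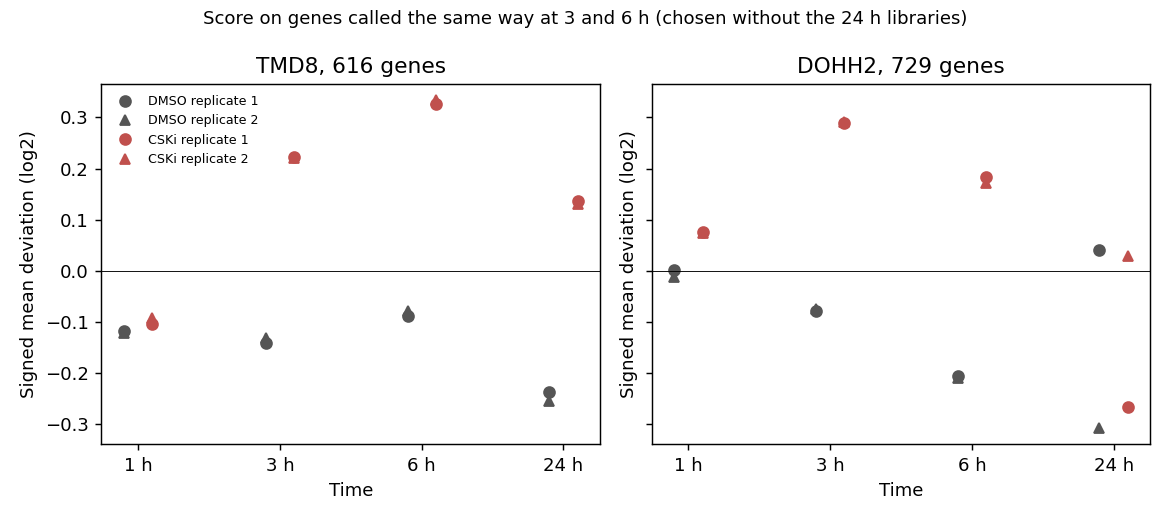
Signed mean log2 deviation (y axis) of each library by time, over 616 genes in TMD8 and 729 in DOHH2 that were called the same way at 3 and 6 h without the 24 h libraries, with DMSO in grey, CSKi in red, circles for replicate 1 and triangles for replicate 2. In TMD8 both CSKi libraries lie above both DMSO libraries at 24 h, and in DOHH2 at 24 h the libraries labelled DMSO replicate 1 and CSKi replicate 2 lie together near 0 and the other 2 together under -0.2.

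Across times in DOHH2, 22 genes were higher and 32 lower at both 3 and 6 h (0.469 and 0.946 for independent lists), and 1 went opposite ways, and without the 24 h libraries 420 were higher and 309 lower at both and 21 went opposite ways. At 1 and 3 h, 4 were higher and 3 lower at both (0.0863 and 0.529 for independent lists) and 2 went opposite ways, and without the 24 h libraries 51 were higher and 49 lower at both and 5 went opposite ways. The size of the response changed over time for 24 genes in DOHH2 with all 4 times, for 972 over 1, 3 and 6 h, and for 9 to 768 when single libraries were left out, with the highest count without the library labelled CSKi replicate 2 at 24 h. CSK and LYN were not called at any time in DOHH2 (CSK from -0.21 to -0.02, LYN from -0.13 to 0.13). They were also not called at the times not named for TMD8, except that CSK at 24 h was called after the GC content and length correction (-0.14, limma adjusted p = 0.000129).

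The responses of the lines were compared as a difference of CSKi effects. EGR3, an early growth response factor, fell further in DOHH2 at 1 h (from 308 to 9.50 mean reads, log2 -4.88) than in TMD8 (from 149 to 66 reads, -0.98), a difference of 3.89 ± 0.47 (n = 2 per group). NR4A1 differed by 1.58 ± 0.29. An induction in vehicle at 1 h, which CSKi may have held back, stays open in both lines. At 3 h the direction was the other way, with EGR2 at -4.51 in TMD8 and 0.02 in DOHH2, where its vehicle level was already lower than at 1 h (difference -4.53 ± 0.30), EGR1 at -2.37 and 0.80 (-3.17 ± 0.61) and the activation marker CD69 at -2.09 and 0.87 (-2.96 ± 0.41). LRRN3 stood at 0.29 in TMD8 and fell in DOHH2 (-1.504, difference 1.79 ± 0.24). PLEKHH3 likewise stood at 0.16 in TMD8 and fell in DOHH2 (-1.08, difference 1.24 ± 0.22). At 6 h EGR2 still differed (-3.18 ± 0.30). ESPNL, an actin-bundling protein gene, stood at 0.59 in TMD8 and -0.95 in DOHH2 (difference 1.54 ± 0.34). Differences passed the test for 17 genes at 1 h, 151 at 3 h and 250 at 6 h, and without the DOHH2 24 h libraries for 53, 576 and 715. Without any 1 of the 8 libraries compared the counts were 5 to 17, 68 to 120 and 138 to 166, and the calls of NR4A1, EGR1 and ESPNL were lost without at least 1 (adjusted p up to 0.212, for NR4A1), while the value of EGR3 ranged from 3.25 to 4.53.

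Several of the genes with large differences had few reads in 1 line. SEMA7A (2.59 ± 0.40 at 1 h) went from 11.5 to 2 mean reads in DOHH2, HMOX1 (2.75 ± 0.58 at 3 h) from 5.50 to 0.5 and LILRA4 (-3.22 ± 0.69 at 6 h) from 3 to 6. TTC9 (-2.73 ± 0.48 at 1 h) went from 4.50 to 0 in TMD8 and GLYATL2 (-4.43 ± 0.49 at 6 h) from 16 to 0.5. FOXO6 (1.95 ± 0.48 at 6 h) had 6 and 8.50 mean reads in TMD8, and PKD1P1 (2.41 ± 0.64 at 6 h), a pseudogene copy of PKD1, had an adjusted p of 0.0499. The calls of TTC9, HMOX1, LILRA4, FOXO6 and PKD1P1 were each lost without at least 4 single libraries (adjusted p up to 0.304, for PKD1P1). Without single libraries the values ranged from 2.00 to 3.51 for HMOX1, -4.37 to -2.07 for LILRA4, 1.34 to 2.56 for FOXO6 and 1.70 to 3.13 for PKD1P1. At 24 h, where the DOHH2 labels are in doubt, 3916 genes differed between the lines. The 6 named by rule were MYO15B (2.91 ± 0.55, from 2.19 to 3.64 without single libraries), GPR55 (2.64 ± 0.62), H2BC8 (HIST1H2BG in the table, 2.62 ± 0.57), ENPP1 (-3.41 ± 0.50), LILRA1 (-2.96 ± 0.63) and YBX3 (CSDA in the table, -2.82 ± 0.57). In DOHH2, 5 of these 6 held at most 13.5 mean reads per group, and LILRA1 held 52.5 and 60.

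Shared genes were counted among 10870 features tested in both lines. At 1 h 3 genes were lower in both, EGR2, DUSP2 and ZFP36L1 (named after their values were seen), where 0.0136 would be shared by independent lists (two-sided Fisher exact p = 1.45e-07, over genes). In the fit without the DOHH2 24 h libraries 4 were lower in both at 1 h, with EGR1 added (-2.48 ± 0.29 in DOHH2). At 3 h 21 were higher and 27 lower in both (2.08 and 5.06 for independent lists) and 6 went opposite ways, and at 6 h 5 were higher and 17 lower (2.00 and 4.20) and 15 went opposite ways. Without the DOHH2 24 h libraries, 69 genes were higher and 94 lower in both at 3 h, and 154 higher and 246 lower at 6 h, while 27 and 107 went opposite ways. Across all genes tested in both, which are not independent replicates, fold changes of the lines correlated with r = 0.154, 0.171 and 0.198 at 1, 3 and 6 h, and r = -0.135 at 24 h for the libraries as labelled.

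Lists of markers of other cell types were not tested, since fewer than 5 members of each passed the filter. In TMD8, the highest were the T cell gene CD8A with 33.0 mean reads per library, COL1A1 with 314, COL1A2 with 46.1 and KRT8 with 26.3, with myeloid genes at most 3.69. In DOHH2, the highest were LYZ with 128 mean reads, NKG7 with 41.8 and CD3E with 17.8, with fibroblast and epithelial genes at most 4.37. None of 9 mitochondrially encoded genes is in the table.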

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

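The differences between lines and over time named here passed planned tests of the difference itself, while the tests of GC content, of scaling and left-out libraries as causes, of short-lived transcripts and of handling at 1 h or on called members were chosen only after their results were seen. Quantile and median scaling and leaving out single libraries were planned as alternatives.

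The response to CSKi differed between the lines for 17 genes at 1 h, 151 at 3 h, 250 at 6 h and 3916 at 24 h. Without the DOHH2 24 h libraries the first 3 counts were 53, 576 and 715. The response changed over time for 4727 genes in TMD8 and 24 in DOHH2, or 972 in DOHH2 over 1, 3 and 6 h. In log2 units, TMD8 minus DOHH2, the differences were EGR3 3.89, SEMA7A 2.59, NR4A1 1.58 and TTC9 -2.73 at 1 h. At 3 h they were HMOX1 2.75, LRRN3 1.79, PLEKHH3 1.24, EGR2 -4.53, EGR1 -3.17 and CD69 -2.96. At 6 h they were PKD1P1 2.41, FOXO6 1.95, ESPNL 1.54, GLYATL2 -4.43, LILRA4 -3.22 and EGR2 -3.18. At 24 h they were MYO15B 2.91, GPR55 2.64, HIST1H2BG 2.62, ENPP1 -3.41, LILRA1 -2.96 and CSDA -2.82. The calls of NR4A1, TTC9, HMOX1, EGR1, PKD1P1, FOXO6, ESPNL and LILRA4 were each lost without at least 1 library.

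In DOHH2 at 24 h, vehicle and treated libraries crossed. On the 729 genes called the same way at 3 and 6 h without the 24 h libraries, the gap between treated and vehicle at 24 h was -0.306 within replicate number 1 and 0.336 within number 2, and the smaller of these was 79.4% of the mean gap at 6 h (0.386). Among 10000 random gene sets of like mean level the number 1 gap lay at percentile 0 and the number 2 gap at percentile 100. The gaps thus touch the genes that the inhibitor changes. Random sets do not hold genes chosen for moving together, so they cannot exclude a culture difference that reaches these genes. The mean signed deviation also moved in vehicle alone, from 0.002 and -0.013 at 1 h to -0.206 and -0.21 at 6 h. An exchange of labels, or of treatments, within replicate number 1 would give gaps of opposite sign, and the 79.4% passed the limit set in advance. The 2 exchanges cannot be separated with these data, from each other or from such a culture difference. The count of 3916 line differences and every DOHH2 value at 24 h carry this doubt, and no relabelled test was made.

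In TMD8 at 24 h, 6486 of 12000 features were called. After a correction for GC content and length 6637 were called, the lowest count over 3 other scalings was 6443, and the lowest without 1 of the 4 libraries was 5241. None of these takes the count near 0.5 of 6486, a limit set after the counts were seen. The size of the count thus does not rest on GC content and length, on the choice among these scalings or on 1 library. All 3 scalings bring the libraries to a common level, so a change in total RNA would not show. Single lists did move, and after quantile normalization 17 of 31 ribosomal protein genes rose and 3 fell. A held-back change of the vehicle cultures from 6 to 24 h was tested by the correlation across genes between vehicle change and inhibitor effect with separate libraries, which was -0.349 in one split and -0.22 in the other. By the limits set in advance this was undecided, so it may account for a part of the response.

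Possible causes of the early fall of immediate early genes in TMD8 include lost signalling, a general loss of short-lived transcripts and an induction by handling in vehicle. These are not all the possible causes, so evidence against 1 of them is not evidence for another. The median log2 fold change at 3 h of 18 short-lived transcripts outside the lists was 0.093 (quartiles -0.147 and 0.14), so they did not fall as a set. Of them 1 was called lower and 2 higher. The 10 immediate early genes called had a median of -1.02. They were chosen for being called, so the gap between these medians cannot decide on a general loss. Against the -0.223 of all 21 tested the lower quartile leaves a small loss open. An induction by handling is argued against for the changes at 3 h. In vehicle the immediate early list differed by a median of 0.135 (quartiles 0.033 and 0.211) between 3 and 6 h. The 20 members of the early lists called lower at 3 h differed by 0.121. For the changes at 1 h an induction by handling stays open, and it was not tested in DOHH2. The 4 members called in TMD8 at 1 h, too few to decide, stood a median of 0.704 higher in vehicle at 1 h than at 6 h. Their values were 1.12 for EGR2, 1.48 for EGR1, 0.23 for TNF and 0.29 for DUSP2, against a median CSKi effect of -1.57. Reduced receptor or Src family signalling was not measured.

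In vehicle, 10697 features differed between the lines, and of 100 splits of the 16 vehicle libraries into 8 and 8 only the real one, 1 of 100, called as many, with 10083 in a 2-group fit against 8616 for the highest other split. The other splits mix 2 different lines, so this outcome was all but fixed in advance. It says nothing on DLBCL type.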

How the results depend on the processing

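The voom alternative, the total mapped scaling, the GC content and length correction and the fit without the 24 h DOHH2 libraries were chosen after the data were seen. The quasi-likelihood count test was not run. With 1 added, 9000 features, median centring, quantile normalization, the replicate block, robust variance or total mapped scaling, all 17 counts of genes stayed within 1.5 times. The cause of the other changes was not tested, except that a stricter threshold calls fewer genes by construction. Duplicates and 12273442 to 24907030 reads limit what small folds can be called.

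Without the variance trend, TMD8 3 h called 338, DOHH2 1 h 27, 3 h 166, 6 h 47, 24 h 1, and the DOHH2 time response 13. With a fold of at least 1.5, TMD8 called 88 at 3 h, 182 at 6 h and 1485 at 24 h, and DOHH2 26, 61 and 33 at 1, 3 and 6 h. The line differences were then 62, 127 and 1347 at 3, 6 and 24 h, the TMD8 time response 1458, vehicle over time 1326 in TMD8 and 701 in DOHH2, and the lines in vehicle 6227. Overlaps were then 5 and 1 between lines at 3 and 6 h, 55 and 107 in TMD8 at 3 to 6 h and 6 to 24 h, and 3 and 9 in DOHH2 at 1 to 3 h and 3 to 6 h. At adjusted p under 0.01, TMD8 called 311 at 3 h and 874 at 6 h, DOHH2 23, 63 and 35 at 1, 3 and 6 h, line differences 6, 63, 114 and 2404, the DOHH2 time response 10 and DOHH2 vehicle 1589. With both lines in 1 fit, TMD8 called 219 at 3 h and 685 at 6 h, and DOHH2 82, 644 and 454. With only the 4 libraries, TMD8 3 h called 1174 and DOHH2 339, 1907 and 1328. Without the filter DOHH2 called 206 at 3 h, 63 at 6 h and 7 at 24 h. By voom, DOHH2 6 h called 216 and the line difference at 1 h 8. Without the 24 h DOHH2 libraries, DOHH2 called 244, 1747 and 1637, line differences 53, 576 and 715, the time response 972 and vehicle 6338, with overlaps of 163 and 400 between lines at 3 and 6 h and 100 and 729 in DOHH2 at 1 to 3 h and 3 to 6 h. Lists called fell from 72 to 21 of 216 with an estimated correlation, all among the 72, and were 69 by fry, 48 of them shared. CSK in TMD8 at 24 h turned from 0.01, not called, to -0.14 after the GC and length correction (adjusted p = 0.000129). Total mapped scaling gave 128 higher and 239 lower at DOHH2 3 h against 148 and 167, and 127 and 71 for the line difference at 3 h against 67 and 84.

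Leave-one-out ranges, with a lone library assumed to vary like the other groups, were 4 to 7, 256 to 315, 836 to 890 and 5241 to 6485 in TMD8 at 1, 3, 6 and 24 h, and 13 to 16, 30 to 87, 9 to 34 and 0 to 647 in DOHH2. Line differences were 5 to 17, 68 to 120, 138 to 166 and 2846 to 5078, time responses 3653 to 5304 in TMD8 and 9 to 768 in DOHH2, vehicle 5837 to 6651 in TMD8 and 1878 to 4093 in DOHH2, and the lines in vehicle 10585 to 10682. Same-number correlations of deviations at 1, 3, 6 and 24 h were 0.068, -0.005, 0.036 and 0.166 in TMD8. In DOHH2 they were 0.027, 0.028, 0.049 and -0.476, the last from the libraries that crossed at 24 h. With 2 libraries per group, low values do not exclude that same-number libraries share more than a number. The replicate block was 1 term over all times, so it did not model pairing within a time. It called 7, 580, 1544 and 6523 in TMD8 and 43, 339, 117 and 0 in DOHH2. The crossed pairing at DOHH2 24 h called 0, where limma without a block called 0 with 378 at an unadjusted p under 0.05.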

Other observations

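All values here come from tables made for the planned comparisons, and their choice was made after the results were seen.

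In TMD8 vehicle at 24 h against 1 h, 12 of 20 ATF4 and amino acid response genes were higher (median log2 0.43), 8 of 9 heat shock genes were higher (median 0.33) and 18 of 21 G1/S genes were higher (median 0.25). In all, 2733 features were higher and 2867 lower in TMD8, and 701 higher and 723 lower in DOHH2, where the labels at 24 h are in doubt.

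In TMD8, BCL2 family genes went both ways from 3 h on. BIK, a pro-apoptotic member, stood at -1.59 ± 0.17 at 3 h and -1.44 ± 0.17 at 6 h, while BMF, another pro-apoptotic member, stood at 0.46 ± 0.06 and 0.65 ± 0.06.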
